A study of Sus scrofa with 12 samples.

How the data were processed

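RNA of OPEC cells was measured on 12 Affymetrix Porcine arrays, 3 each for cells alone and for co-incubation with bacteria, sperm or red blood cells. The intensity values were used as deposited, and per the submitters' processing notes they are MAS5 5.1 signals on a linear scale. The 2% trimmed mean was 100.03 on every array, so the arrays had been scaled to one level. No detection calls were used. Groups were read from the sample labels, and 0 columns of other samples were left out.

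The table held 24123 probe sets. The 124 AFFX control probe sets and the 30% of the others with the lowest mean were left out, which left 16799. The annotation listed 10297 probe sets, 10099 with 1 gene symbol and 198 with several, and 13826 were not listed. Symbols of 9989 probe sets were matched through the entrez id and 0 changed. Of the tested probe sets, 7900 had 1 symbol.

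Values were analysed as log2(value + 16) with limma 3.58.1 in R 4.3.3, with 1 mean per group in a single fit of all arrays. The 6 comparisons between groups and a moderated F test were two-sided, with the Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Residual degrees of freedom were 8 and the prior added 4.37. Intervals are 95% intervals of the log2 difference, and signals are means ± SD on the linear scale. The median residual SD fell from 0.660 (log2) for the dimmest tested probe sets to 0.279 for the 2400 brightest. Signals of 17 Tag control probe sets, which have no porcine target, lay between 1 and 95.5, and 10925 of the tested probe sets had a mean below the highest of these.

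Gene lists were tested with camera at a preset correlation of 0.01, with 1 probe set per gene, the brightest, over 5749 genes. The 24 lists needed at least 5 measured genes, and p values were adjusted over the lists within a comparison. The choice of comparisons, tests, lists and genes to name was fixed before the data were examined. For each comparison with cells alone, up to 10 genes per direction were to be named among those past the threshold with 1 symbol and all 3 arrays on one side of the other 3. Where fewer than 5 passed, the list was filled to 5 with the smallest unadjusted p. Between co-incubations the numbers were 5 and 3. Up to 4 members of each list per comparison could be named as well. KRT18, FTH1, OVGP1, HMOX1, PRM2, LDHC, AHSP and the genes of replicate 1 lie outside this rule and were chosen after their values were seen.

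Correlations and overlaps of the 3 comparisons with cells alone were set beside 100 simulated draws of unchanged groups that share the controls. The fit was tested on simulated data with 200 changed probe sets in 5 simulations, and camera with a simulated shift of one list.

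Alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no filter, the lowest 50% left out, trend and robust priors, array weights, the replicate number as a block, only the 2 groups compared, and each array left out. For the lists, an estimated correlation, fry and all probe sets per gene were tried. Replicate 1 as a batch term, replicates 2 and 3 alone, the lowest 75% or 90% left out, and the filters crossed with the designs were chosen after seeing the data. The comparison of replicate 1 with replicates 2 and 3, adjusted for group, was also chosen after seeing the data, as were its differences within groups and in control probe sets, the splits of the arrays in the 2400 brightest probe sets, and the splits that keep 1 array of each replicate number in each group.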

Results

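Gene expression was measured in OPEC, a porcine oviductal epithelial cell line, after 24 h in culture alone or with 1 of 3 additions. The title of the study asks whether the maternal tract tells spermatozoa from other entities. The additions were 100000000 bacteria, 1000000 spermatozoa per ml or 5000000 red blood cells per ml. The labels describe the bacteria as Escherichia coli, the spermatozoa as boar and the red blood cells as sow. Each of the 4 groups had 3 arrays, described as biological replicates, which gave 12 Affymetrix Porcine arrays. The number of arrays limits the precision of every value. The median signal per array lay between 37.1 and 42.8 and the upper quartile between 93.8 and 103.6. No 2 arrays held identical values. As a check on RNA quality, the log2 ratio of 3-prime to 5-prime probe sets was 3.75 to 4.41 for GAPDH on the 12 arrays. For EEF1A1 it was 0.139 to 1.56, highest in bacteria replicate 2. Pearson correlations of the log2 signals across probe sets were 0.870 to 0.884 within groups and 0.866 to 0.888 between groups. Probe sets are not independent replicates.

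KRT18, a keratin of simple epithelia, had signals from 5133 to 7857 on the 12 arrays. Its log2 fold change against cells alone was 0.24 with bacteria (95% interval -0.30 to 0.79), 0.14 with sperm (-0.41 to 0.68) and 0.09 with red blood cells (-0.45 to 0.64). FTH1, the ferritin heavy chain, had a mean signal of 39214 ± 8980 (SD, n = 3) in cells alone. Its log2 fold change was -0.12 with bacteria, 0.17 with sperm and -0.53 with red blood cells, and the last had an interval of -1.32 to 0.26. OVGP1, the oviductal glycoprotein, varied widely within groups, at 177 ± 65.2 in cells alone and 124 ± 95.8 with sperm.

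None of the 6 comparisons between groups gave a probe set past an adjusted p of 0.05. Of 16799 probe sets tested with limma, 809 to 896 per comparison had an unadjusted p under 0.05, where 5% of them is 839.95. This fit does not model the replicate number, so variation shared by same-numbered arrays stays in its residual. The 5% is therefore not its exact chance level, and with the replicate number as a block the counts were 892 to 1012. The total without the block joins 6.10% to 7.54% per comparison in the dimmest 4800 tested probe sets and 0.5% to 1.67% in the 2400 brightest. The 2400 brightest were also fitted with replicate 1 as a batch term, chosen after seeing the data. Against cells alone, 184 with bacteria, 163 with sperm and 181 with red blood cells had an unadjusted p under 0.05. Of the 2400, 5% is 120. Other splits that keep 1 replicate 1 array on each side gave 74 to 117, 85 to 232 and 104 to 124 in turn. A fit of the same 2400 without the batch term gave 125, 90 and 120. That fit leaves the variation of replicate 1 in its residual, so its lower counts do not show that the term made the excess. With the batch term, the share was 5.04% for sperm against bacteria, 6.58% for sperm against red blood cells and 5.125% for bacteria against red blood cells. In that setting 3 probe sets passed for bacteria against cells alone, among them SRRM2, a splicing protein, at 1459 ± 247 against 3437 ± 699.6 (n = 3). None passed in the 5 others.

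The moderated F test over the 4 groups also passed 0 probe sets, with 908 at an unadjusted p under 0.05 and a smallest adjusted p of 0.331. Of 100 splits of the arrays that keep 1 array of each replicate number in each group, the real one included, 4 gave at least 908, a test chosen after seeing the data. In the comparisons with cells alone, some probe sets had all 3 co-incubated arrays on one side of all 3 controls. Their share was 10.1% with bacteria, 9.72% with sperm and 9.76% with red blood cells. Chance gives 10% only if the arrays of the groups compared are interchangeable. Each group holds 1 array of each replicate number, and variation shared by same-numbered arrays makes such separation rarer. The 10% is therefore not the exact chance level, and these shares do not show an absence of differences. In simulated data for bacteria against cells alone with 200 changed probe sets among the 16799, the test recovered 0.1% of 2-fold changes, 64% of 4-fold changes and 95.9% of 8-fold changes. The simulation had no batch term and used all tested probe sets, so it gives no limit for other designs.

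**Figure D1:**
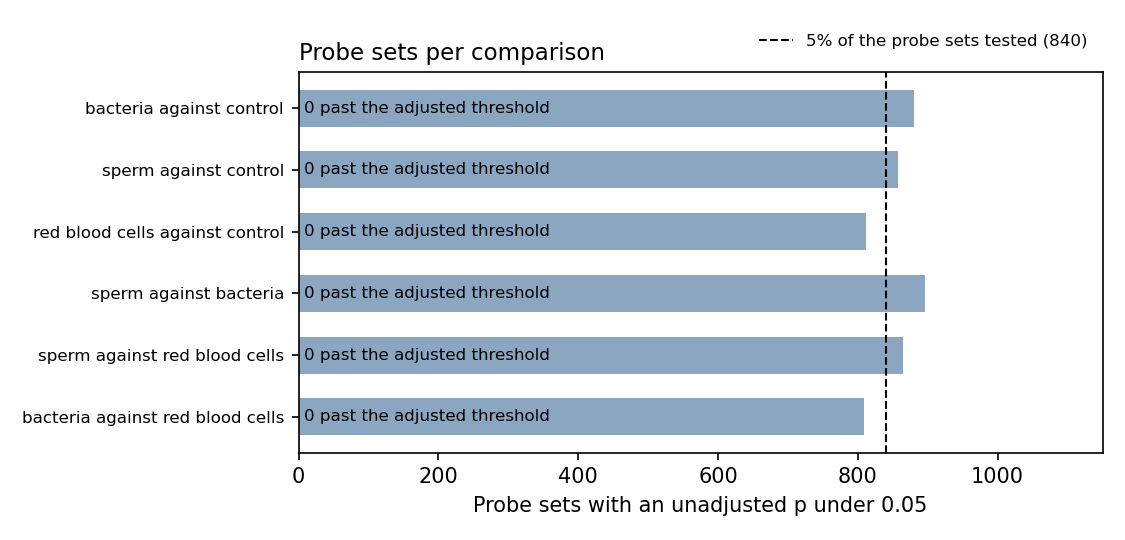
Bars give the number of probe sets with an unadjusted p under 0.05 in each of the 6 comparisons, on a linear axis from 0, and the dashed line marks 5% of the 16799 probe sets tested. The bars lie between 809 and 896, around the line at 839.95, and no probe set passed the adjusted threshold in any of them.

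Replicate 1 of all 4 groups stood apart from replicates 2 and 3. FOS, an immediate-early transcription factor, had a mean signal of 21977 ± 8526 (SD, n = 4) in the replicate 1 arrays and 1515 ± 563 (n = 8) in the others. The log2 difference after adjustment for group was 3.81, with a limma adjusted p of 0.000498. EGR1, at 1187 ± 165 against 338 ± 89.9, and NR4A2, at 1293 ± 196 against 410.3 ± 65.6, were also higher, as were JUN and IER5. A brighter EGR1 probe set, at 3885 against 2081, had a log2 difference of 0.92 and did not pass (adjusted p of 0.0855). Of the stress genes, HSP70.2, an inducible cytosolic chaperone, had 50330 ± 9339 against 13541 ± 2572. HSPA5, the chaperone of the endoplasmic reticulum, had 6576 ± 1982 against 2155 ± 217, and DDIT3, DNAJB1 and GADD45A were higher too. CIC, NCOA1, APPBP2 and RBBP6 were lower in replicate 1. In all, 88 probe sets passed, 34 higher and 54 lower, and 1613 had an unadjusted p under 0.05. This contrast was chosen after the principal components were seen, and it fell to 7 probe sets without control replicate 1, 11 without bacteria replicate 1, 22 without red blood cell replicate 1 and 24 without sperm replicate 1. FOS passed in each of these, while HSP70.2 did not pass without control replicate 1, and HSPA5 did not pass without control, bacteria or red blood cell replicate 1. The log2 differences stayed close to those of all arrays, at 1.80 against 1.90 for HSP70.2 without control replicate 1, and for HSPA5 at 1.38, 1.63 and 1.61 against 1.57.

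Among the 24 gene lists, 3 were higher in replicate 1 by camera. The immediate-early genes had a mean log2 difference of 0.80 over 18 genes, with an adjusted p of 5.11e-08, which was 0.00957 with an estimated correlation. Of these 18 genes, 4 passed over all probe sets and 7 passed adjusted over the list alone. The cytosolic heat shock list had a mean of 0.47 over 17 genes and an adjusted p of 0.00297, and the endoplasmic reticulum stress list a mean of 0.36 over 20 genes and an adjusted p of 0.0109. Their calls were lost with an estimated correlation, at an adjusted p of 0.0665 for heat shock and an adjusted p of 0.0804 for endoplasmic reticulum stress. Within the 4 groups, without a test, the mean of replicate 1 minus replicates 2 and 3 was 0.49 to 1.06 for the immediate-early genes, 0.32 to 0.66 for heat shock and 0.22 to 0.46 for endoplasmic reticulum stress.

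**Figure D2:**
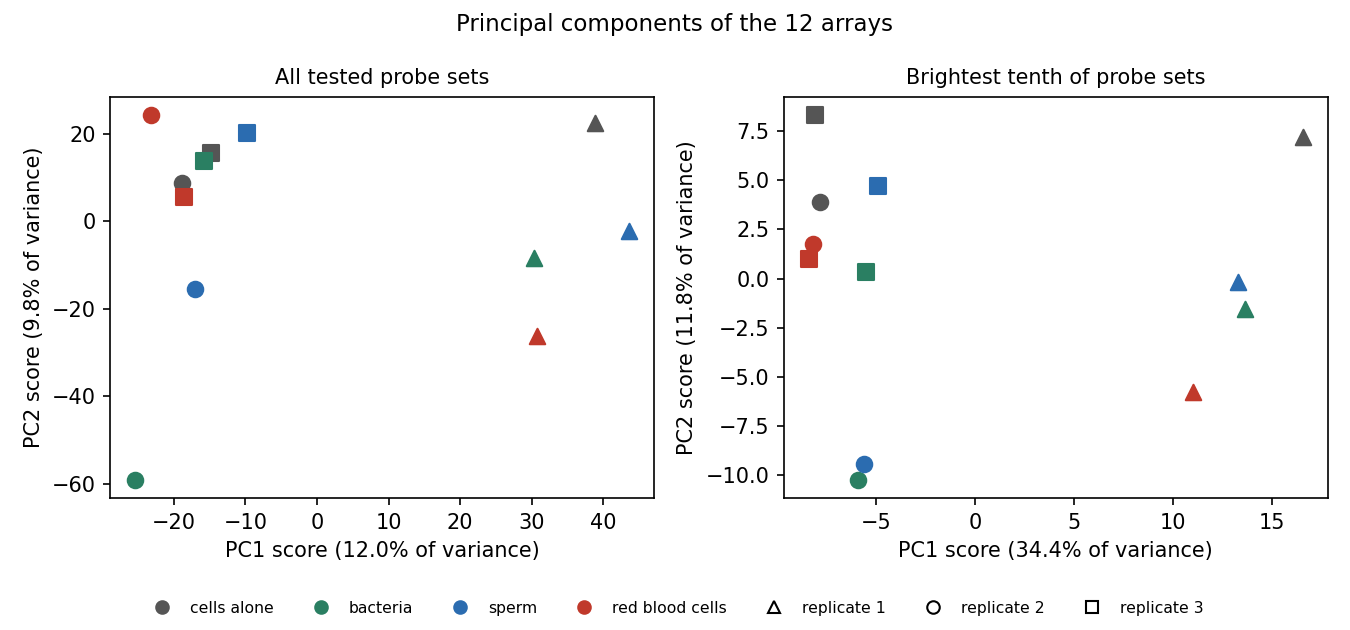
Scores on the first and second principal components of the 12 arrays, with groups as colours and replicate numbers as symbols, for the 16799 tested probe sets (left) and the 2400 brightest (right). The 4 replicate 1 arrays have the highest scores on the first component in both panels, which holds 12.0% and 34.4% of the variance.

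**Figure D3:**
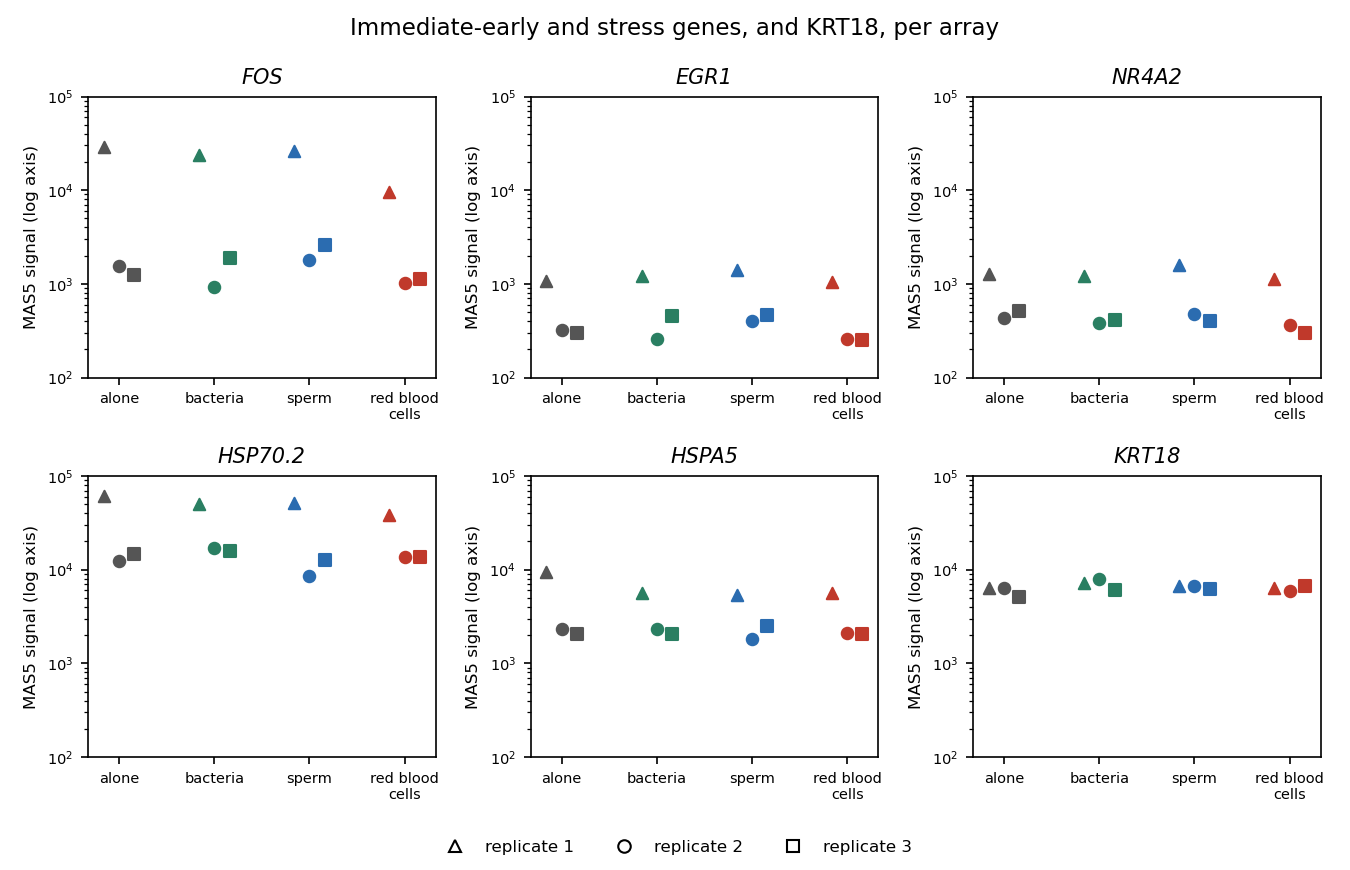
MAS5 signal on a log axis of 5 immediate-early and stress genes and of KRT18 on each of the 12 arrays, by group, with symbols for the replicate number. FOS is at 9579 or more on every replicate 1 array and at 2589 or less on every other array, while KRT18 stays between 5133 and 7857.

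Bacteria against cells alone asks what the epithelial cells do with a microbe. The gene with the smallest p among those higher was CCT6A, a subunit of the cytosolic chaperonin, at 49.8 ± 7.20 (SD, n = 3) with bacteria and 9.17 ± 2.99 in cells alone. The log2 fold change was 1.39, with a 95% interval of 0.79 to 1.99. NPPC, which encodes C-type natriuretic peptide, had a log2 fold change of 2.03, and TBCA, a tubulin-folding cofactor, had 234 ± 40.1 against 65.4 ± 14.6. CLEC1A and SH3GL1 completed the 5 higher genes. On the lower side, NDUFV3, a subunit of respiratory complex I, had 13.3 ± 5.77 against 86.5 ± 25.2, a log2 fold change of -1.79. MFAP1, a component of the spliceosome, had a log2 fold change of -2.12, and CELF4, TTI1 and FAM107B were the other lower genes.

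None of these 10 genes passed, with limma adjusted p from 0.428 to 0.632. Limma passed 0 probe sets and 881 had an unadjusted p under 0.05, 387 higher and 494 lower. The other probe sets of CCT6A had log2 fold changes of 0.14 and -0.15 in this comparison, and those of TTI1 and CELF4 0.14 and 0.06. The other FAM107B probe set went the other way, at 56.4 ± 33.5 against 19.0 ± 14.3. With replicate 1 as a batch term, an alternative chosen after seeing the data, 0 passed and 946 had an unadjusted p under 0.05, and in replicates 2 and 3 alone 0 passed and 937 did.

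No immune list passed with bacteria. Of the 17 measured inflammatory cytokine and NF-kB target genes, 11 had a positive fold change and none passed, and the mean was 0.16, with a camera adjusted p of 0.963. CCL4 had 132 ± 21.1 against 84.2 ± 15.4, and ICAM1 had 70.17 ± 1.59 against 97.2 ± 14.0. The interferon-stimulated genes had a mean of -0.08, the pattern-recognition receptors 0.01, the antimicrobial, acute-phase and complement genes -0.10 and antigen presentation 0.14. LTF, the iron-binding antimicrobial protein lactoferrin, had 15.9 ± 13.0 against 81.8 ± 33.9, with an adjusted p of 0.0847 over its list alone. Smallest adjusted p values over the 24 lists were 0.724, for endoplasmic reticulum stress (mean -0.15), hypoxia and glycolysis (0.18) and growth factors and their binding proteins (-0.20). For the endoplasmic reticulum stress list, and for the immediate-early (-0.04) and heat shock (-0.02) lists, replicate 1 lay above replicates 2 and 3 over the 4 groups, by 0.36, 0.80 and 0.47, although the calls for endoplasmic reticulum stress and heat shock were lost with an estimated correlation. MCM4, a replicative helicase subunit of the cell cycle list, had 301 ± 46.3 against 119 ± 108. Over the list alone, 0 members of any list passed.

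Sperm against cells alone asks what the epithelial cells do with spermatozoa. CCT6A had a signal of 71.5 ± 10.2 (SD, n = 3) with sperm and 9.17 ± 2.99 in cells alone, a log2 fold change of 1.80 with an interval of 1.20 to 2.40. DHX30, an RNA helicase, had 188 ± 23.5 against 38.6 ± 16.8. FKBP1A, a prolyl isomerase that binds FK506, had 168 ± 13.4 against 28.3 ± 9.18, a log2 fold change of 2.07 with an interval of 1.28 to 2.87. SDE2 had a log2 fold change of 2.12 and TBCA 1.80. The lower genes were NDUFV3 at 10.9 ± 0.777 against 86.5 ± 25.2, ATL3, which shapes the endoplasmic reticulum, the splicing factor SRSF10, the magnesium transporter SLC41A1 and CELF4. Their log2 fold changes lay between -1.90 and -1.40.

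None of the 10 passed, with limma adjusted p from 0.214 to 0.478. Limma passed 0 probe sets and 857 had an unadjusted p under 0.05. A pseudocount of 1 in place of 16 passed 2, CCT6A, with a log2 fold change of 2.86 and a limma adjusted p of 0.0363, and ATL3, with -3.38 and 0.0137. Both signals of ATL3, 2.73 ± 0.153 and 38.4 ± 8.60, lay below the highest signal of the control probe sets without a porcine target, 95.5. So did both of CCT6A, 71.5 ± 10.2 and 9.17 ± 2.99, whose other probe sets had log2 fold changes of 0.31 and -0.02. The other probe sets of DHX30 had log2 fold changes of -0.07 and 0.39, and those of SRSF10 that were brighter, at 562 to 1481 with sperm, had -0.17, 0.31 and -0.14. With replicate 1 as a batch term 0 passed and 930 had an unadjusted p under 0.05, and in replicates 2 and 3 alone 0 passed and 896 did.

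Of the stress lists, oxidative stress and NRF2 targets had a mean of 0.08 with sperm, and 14 of its 21 genes had a positive fold change. GSR, the glutathione reductase, had 118 ± 36.8 against 24.5 ± 7.91, a log2 fold change of 1.70. It did not pass over all probe sets and passed adjusted over the list alone, at 0.0381. The growth factors and their binding proteins had a mean of -0.22 with 15 of 22 negative, and INHBB, a subunit of activins and inhibins, had 8.70 ± 2.09 against 48.7 ± 10.9. Oviduct secretory cell genes and sperm-binding proteins had a mean of -0.16 over 23 genes, and PTGS1, a cyclooxygenase, had 38.7 ± 11.2 against 93.1 ± 19.1. In hypoxia and glycolysis, with a mean of -0.08, SLC2A1, a glucose transporter, had 160.2 ± 7.36 against 61.9 ± 23.9. INHBB, PTGS1 and SLC2A1 were named for a small p within their lists. They passed neither over all probe sets nor over their lists alone. Both means of INHBB and of PTGS1 lay below 95.5, the highest signal of the control probe sets without a porcine target. Cholesterol synthesis had a mean of 0.09, epithelial junctions and keratins 0.12, and the inflammatory list -0.05. The immediate-early, heat shock and endoplasmic reticulum stress lists, higher in replicate 1, had means of 0.01, -0.09 and -0.00, and the replicate 1 calls of the last 2 were lost with an estimated correlation. All 24 lists had adjusted p values of 0.976 or more.

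Transcripts of spermatozoa did not stand out in the sperm group. The spermatozoa and testis list had a mean of 0.09 over 12 measured genes, with a camera adjusted p of 0.976. PRM2, a protamine, had 206 ± 71.1 with sperm, 167 ± 11.2 in cells alone and 229 ± 10.3 with red blood cells. LDHC, the testis lactate dehydrogenase, had 88.3 ± 24.3 with sperm and 59.8 ± 12.5 in cells alone.

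Red blood cells against cells alone sets a non-pathogenic cell beside the other additions. CCT6A had 57.3 ± 18.3 (SD, n = 3) against 9.17 ± 2.99, and MRPL3, a protein of the mitochondrial ribosome, had 64.7 ± 6.97 against 9.73 ± 10.7. CCNL2, a cyclin linked to splicing, had 76.7 ± 9.95 against 20.2 ± 8.64, and DHX30 and CLEC1A were the other higher genes. Among the lower genes, EPB41L2, a membrane skeleton protein, had 5.50 ± 2.81 against 78.8 ± 24.5, a log2 fold change of -2.11 with an interval of -3.03 to -1.19. TADA2A, NDUFV3, DHRS1 and LMBR1L had log2 fold changes from -1.86 to -1.29. Other MRPL3 probe sets had log2 fold changes of -0.77 and 0.18, where that of the named one was 1.72.

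None of the 10 passed, with limma adjusted p from 0.636 to 0.653. Limma passed 0 probe sets and 811 had an unadjusted p under 0.05. Without red blood cell replicate 1, 1 probe set passed, of OAZ1, the ornithine decarboxylase antizyme (log2 fold change 5.81, adjusted p = 0.00493). Its signals with red blood cells were 85.4, 1355 and 4644, against a mean of 31.3 ± 18.1 in cells alone. A brighter OAZ1 probe set had 17388 ± 1586 against 17913 ± 1578. With replicate 1 as a batch term 0 passed and 874 had an unadjusted p under 0.05, and in replicates 2 and 3 alone 0 passed and 836 did.

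The inflammatory list held 1 member that passed adjusted over the list alone with red blood cells. CXCL8, the neutrophil chemokine interleukin 8, had 129.9 ± 95.5 against 12.7 ± 10.6, a log2 fold change of 2.15 with an interval of 1.02 to 3.27. Its adjusted p was 0.0222 over the list and 0.739 over all probe sets. The signals were 32.3, 223 and 134 with red blood cells and 0.7 to 20.6 on the 9 other arrays. Oxidative stress and NRF2 targets had a mean of 0.24 with 17 of 21 positive and an adjusted p of 0.116. GSR had 103 ± 23.1 against 24.5 ± 7.91, at an adjusted p of 0.0706 over its list alone. Growth factors and their binding proteins had a mean of -0.30 with 17 of 22 negative and an adjusted p of 0.116. IGFBP1 had 22.9 ± 7.27 against 100.7 ± 53.2 and passed neither over all probe sets nor over its list alone. Without control replicate 1 the NRF2 list passed (mean 0.33, adjusted p = 0.0478), and over the 4 groups this list had a mean of 0.23 in replicate 1 against replicates 2 and 3 (camera adjusted p of 0.0520). Without red blood cell replicate 1 the endoplasmic reticulum stress list passed (mean -0.36, adjusted p = 0.0208). That list, at -0.11 over all arrays, was higher in replicate 1 by camera, as were immediate-early genes (-0.12) and heat shock (-0.10), although for heat shock and endoplasmic reticulum stress the call was lost with an estimated correlation.

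The list of genes that handle heme and iron did not pass with red blood cells. The list had a mean of -0.05 over 17 genes, with 9 positive (adjusted p = 0.859). HMOX1, the inducible heme oxygenase, had 321 ± 45.0 with red blood cells and 367 ± 166 in cells alone, a log2 fold change of -0.11 with an interval of -0.80 to 0.59. The erythroid list had a mean of -0.01 over 8 genes. AHSP, an erythroid gene left out by the filter, had 7.1, 52 and 52.3 with red blood cells against 4.5 to 14.2 without them, and CXCL8 and the dimmer OAZ1 probe set were highest in the same 2 arrays. All of these AHSP signals lay below 95.5, the highest signal of the control probe sets without a porcine target. The fibroblast and smooth muscle list had a mean of -0.32 with 11 of 15 negative and an adjusted p of 0.416. COL3A1, a fibrillar collagen, had 13.9 ± 3.44 against 69.1 ± 17.3, both below 95.5. It passed neither over all probe sets nor over its list alone. Leukocyte genes had a mean of -0.05 and ciliated cell genes -0.17.

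Lists not described so far gave means close to 0 against cells alone. For bacteria, sperm and red blood cells in turn, oxidative phosphorylation had means of 0.02, -0.03 and -0.07, and the cell cycle list 0.12, -0.05 and -0.01. The p53 and apoptosis list had 0.04, 0.00 and 0.09, and extracellular matrix genes 0.05, -0.07 and 0.05. Over the 6 comparisons, 0 of 144 tests of a list passed by camera with the preset correlation, with an estimated correlation or by fry, and 6 had an unadjusted camera p under 0.05. In 6 of the 144 a member passed adjusted over its list alone, and a threshold of 0.05 in each list lets some pass by chance. Means lay between -0.32 and 0.25. Mean and median differed in sign in 34 of the 144 tests, and mean and camera direction in 17. Camera recovered a simulated shift of 0.5 in the cell cycle list for sperm against cells alone, at an adjusted p of 3.80e-07 over 5749 genes.

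**Figure D4:**
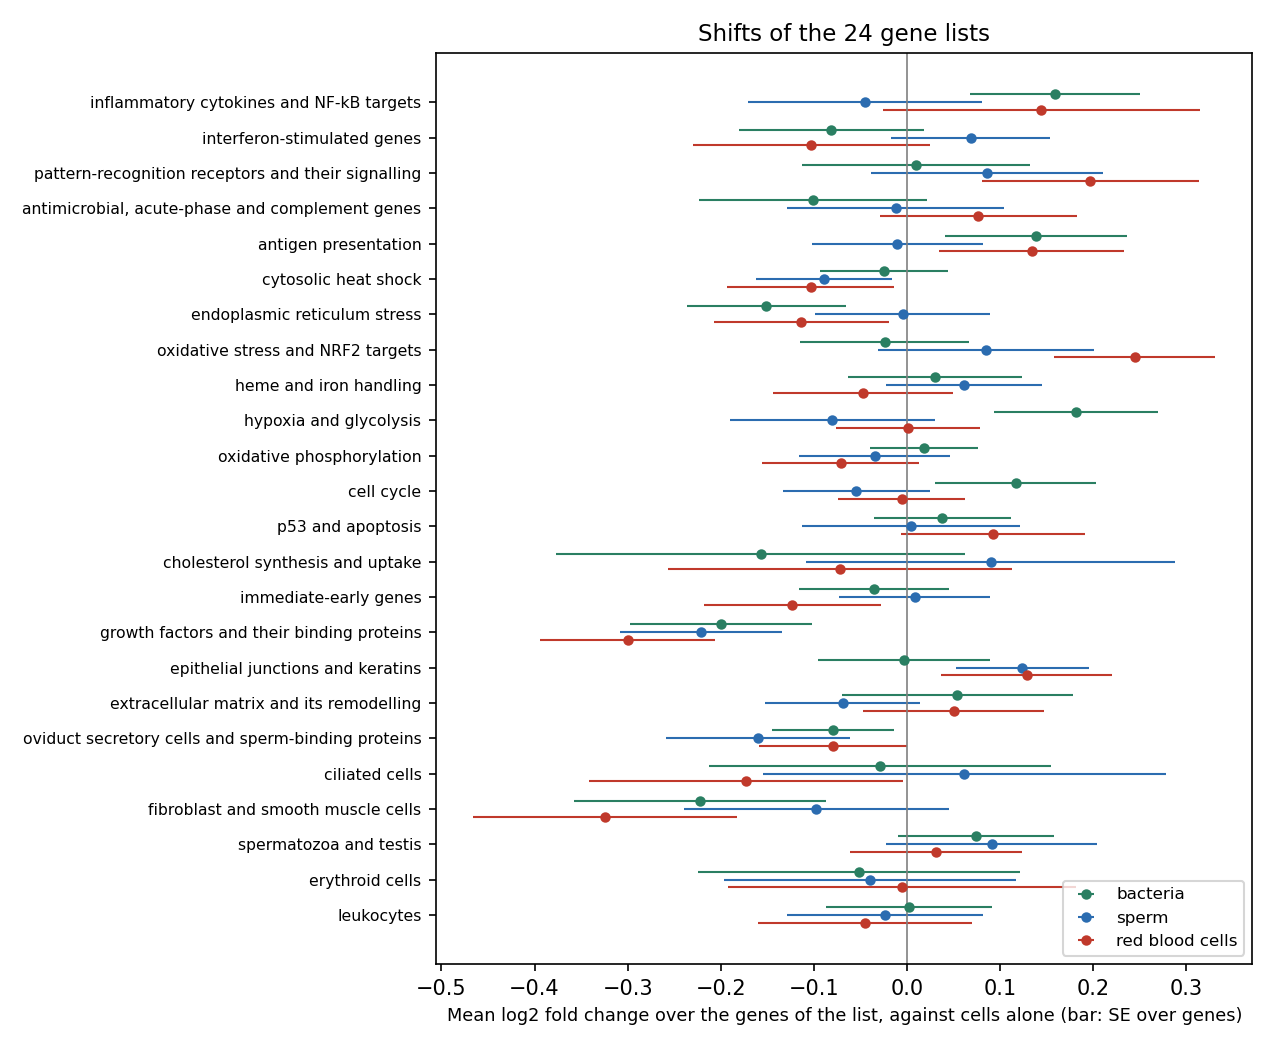
Mean log2 fold change over the measured genes of each of the 24 lists against cells alone, with bars for the standard error over genes and a colour for each addition. Means lie between -0.32 and 0.24 and none passed the adjusted threshold.

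Sperm against bacteria addresses the title's question most directly, with sperm set against a microbe. FAM107B had 67.8 ± 18.0 (SD, n = 3) with sperm and 8.80 ± 3.14 with bacteria, and PIP5K1A, a lipid kinase, had 60.1 ± 15.9 against 5.37 ± 0.651. SDE2 was the other higher gene. SLC41A1 had 11.5 ± 5.00 with sperm and 89.4 ± 8.07 with bacteria, a log2 difference of -1.95 with an interval of -2.64 to -1.27. SRSF10 had 7.10 ± 0.889 against 67.7 ± 4.62, and TTLL1, a tubulin polyglutamylase, had 8.40 ± 2.36 against 83.5 ± 27.0. The other FAM107B probe set had a log2 difference of -0.66, where the named one had 1.74, and the 3 others of SLC41A1 had 0.12, -0.44 and 1.10. Of the lists, hypoxia and glycolysis had a mean of -0.26 with 16 of 22 negative (adjusted p = 0.374), cholesterol synthesis 0.25 with 9 of 11 positive (0.431) and the inflammatory list -0.20 (0.458). None of the 6 genes passed, with limma adjusted p from 0.233 to 0.39. Limma passed 0 probe sets and 896 had an unadjusted p under 0.05. A pseudocount of 1 passed 3, of SRSF10 (adjusted p = 0.0445), ATL3 (0.0177) and a probe set without a gene symbol (0.0499). With replicate 1 as a batch term 0 passed and 982 had an unadjusted p under 0.05, and in replicates 2 and 3 alone 0 passed and 985 did.

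Sperm against red blood cells had the smallest adjusted p of the 6 comparisons. CCNL2 had 6.07 ± 6.18 (SD, n = 3) with sperm and 76.7 ± 9.95 with red blood cells, a log2 difference of -2.10 with an interval of -2.73 to -1.47. SRSF10 had 7.10 ± 0.889 against 80.8 ± 6.46, a difference of -2.07, and both had a limma adjusted p of 0.142. BZW1 was the third lower gene, while its brightest probe set had a log2 difference of 0.07. FKBP1A, at 168 ± 13.4 against 35.3 ± 9.85, SDE2 and TF, which encodes transferrin, were higher with sperm. CXCL8 was lower with sperm and DDX58, the RNA sensor RIG-I, higher, at adjusted p of 0.00586 and 0.0260 over their lists alone. DDX58 had 56.8 ± 3.38 against 17.0 ± 13.6, both below 95.5, the highest signal of the control probe sets without a porcine target. All 24 lists had adjusted p values of 0.834 or more. Limma passed 0 probe sets and 865 had an unadjusted p under 0.05. A pseudocount of 1 passed 2, SRSF10 and ATL3, each at an adjusted p of 0.0214, and leaving out red blood cell replicate 1 passed 1, the dimmer OAZ1 probe set (adjusted p = 0.00159). With replicate 1 as a batch term 0 passed and 957 had an unadjusted p under 0.05, and in replicates 2 and 3 alone 0 passed and 891 did.

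Bacteria against red blood cells compares the additions other than sperm. IHH, a hedgehog ligand, had 144 ± 43.4 (SD, n = 3) with bacteria and 31.1 ± 5.41 with red blood cells, and TADA2A and DDX58 were also higher with bacteria. TCEA1, a transcription elongation factor, was lower, with a log2 difference of -1.98. The dimmer OAZ1 probe set had a log2 difference of -4.97, with an interval of -7.13 to -2.81, and DEUP1, which acts in multiciliated cells, -2.09. CXCL8 and DDX58 passed adjusted over their lists alone, at 0.00962 and 0.0211. DDX58 had 58.7 ± 7.11 against 17.0 ± 13.6, both below the highest signal of the control probe sets without a porcine target. Oxidative stress and NRF2 targets had a mean of -0.27 with 16 of 21 negative (camera adjusted p = 0.483). None of the 6 named genes passed over all probe sets, with limma adjusted p from 0.547 to 0.614. Limma passed 0 probe sets and 809 had an unadjusted p under 0.05. Without red blood cell replicate 1 the dimmer OAZ1 probe set passed (log2 difference -6.52, adjusted p = 0.0015). With replicate 1 as a batch term 0 passed and 871 had an unadjusted p under 0.05, and in replicates 2 and 3 alone 0 passed and 965 did.

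**Figure D5:**
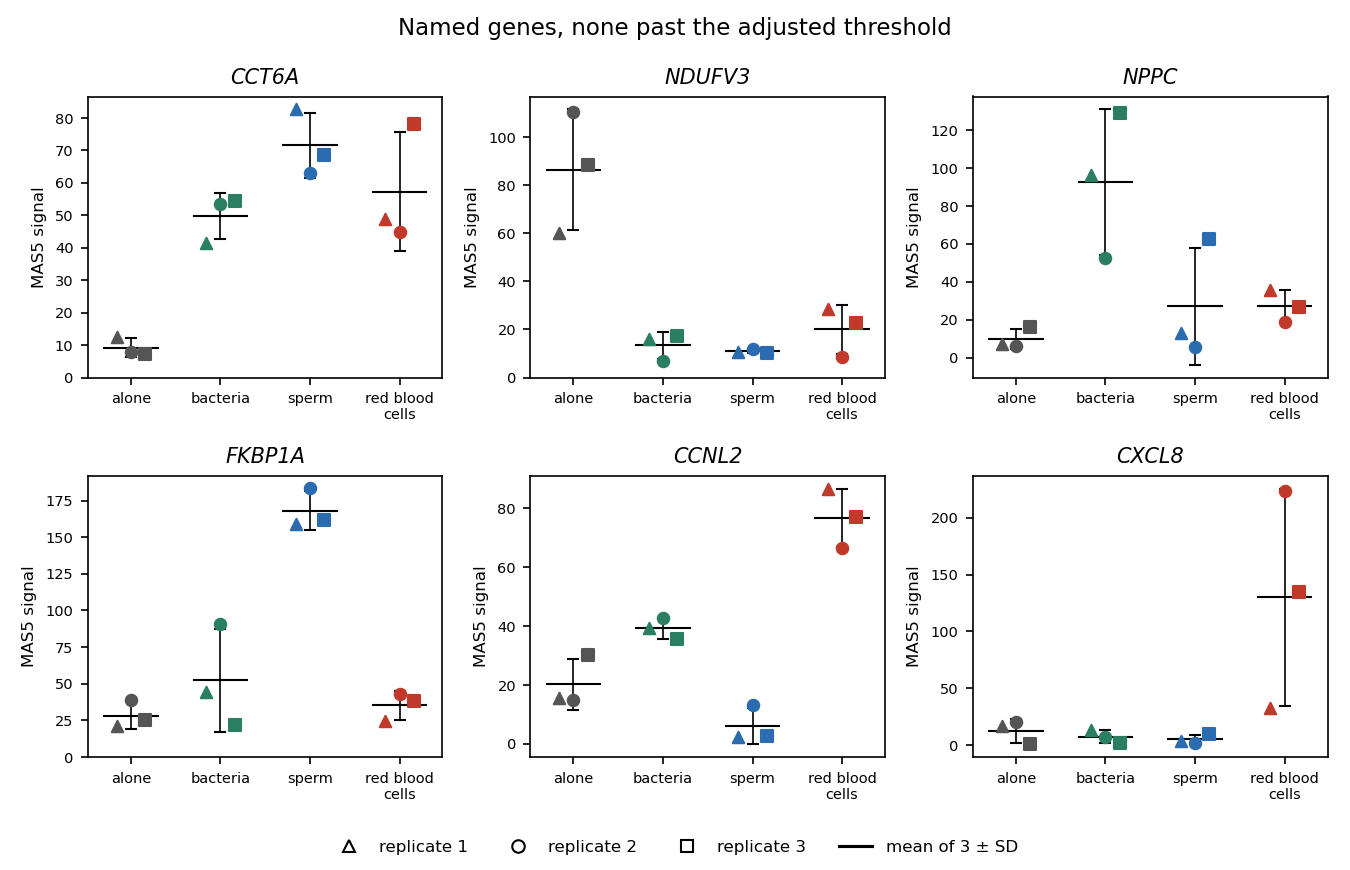
MAS5 signal on each of the 12 arrays of 6 genes named in the comparisons, by group, with symbols for the replicate number and a line and bar for the mean of 3 ± SD. CCT6A lies at 7.1 to 12.6 in cells alone and at 41.5 to 82.8 in the other groups, and none of the 6 genes passed the adjusted threshold over all probe sets.

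The 3 responses correlated as closely as their common control arrays alone give. The log2 fold changes of bacteria and sperm correlated at r = 0.50 across probe sets, those of bacteria and red blood cells at 0.51, and those of sperm and red blood cells at 0.49. Unchanged groups simulated against the same controls gave 0.50 in 100 draws. The covariances differed from the simulated ones by -0.00136, -0.000662 and -0.00357. The simulated spread includes differences between replicate numbers, which cancel in the real fold changes. The simulated covariances are thus too high as a level for no response, and these differences do not exclude a shared one. No probe set passed in more than 1 comparison, as none passed. At an unadjusted p under 0.05, bacteria and sperm shared 120 higher and 90 lower probe sets, against 106 and 105 in the simulated groups and 10.6 and 11.7 for independent lists. Bacteria and red blood cells shared 125 higher and 105 lower, against 105 and 104 simulated, and sperm and red blood cells 133 higher and 67 lower, against 105 and 105 simulated. Probe sets at that level in all 3 comparisons numbered 97, against a mean of 88.0 and a range of 62 to 112 in the simulated groups. Of these, 65 were higher, CCT6A among them, against 28 to 64 simulated, and 30 lower, NDUFV3 among them, against 30 to 61 simulated. The simulated values were normal and independent between probe sets and arrays, so their range understates the spread of such counts where probe sets vary together. In 100 splits of the real arrays that keep 1 array of each replicate number in each group, the real one included and chosen after seeing the data, 29 gave at least 65 higher and 84 gave at most 30 lower. The other splits gave correlations between 0.462 and 0.530.

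Most of the named differences lay at low signal. Of 51 differences in other probe sets of the named genes, 25 had the direction of the named probe set and 26 the opposite one, and 0 had a 95% interval without 0. Of the 48 gene and comparison pairs named by the fixed rule, 38 had both group means below 95.5, the highest signal of 17 control probe sets without a porcine target. An exact test of 3 arrays against 3 cannot give a p below 0.1. An adjusted p above 0.05 does not show that groups were equal. Fold changes and intervals are on the log2(value + 16) scale, which understates changes of dim genes, so the intervals do not bound those on other scales.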

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

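The tests on replicate 1, on OAZ1 and CXCL8 and on splits of the arrays were chosen after the results were seen, except that of the other OAZ1 probe set, whose prediction was written first. Poly-A spikes, bacterial transcripts added to each sample during labelling, lay above every control array on 6 of the 9 co-incubated arrays, a signal in probe sets that the comparisons do not use. The fold over the control mean was 1.32 in bacteria replicate 1, 1.96 in bacteria replicate 2, 2.63 in sperm replicate 1, 1.43 in sperm replicate 2, 1.69 in red blood cell replicate 1 and 1.26 in red blood cell replicate 2. Control arrays lay between 0.871 and 1.20. Groups of 3 arrays were not tested for outliers.

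Replicate 1 of all groups stood apart, with FOS, HSP70.2 and HSPA5 higher. FOS passed with each array left out in turn, while HSP70.2 did not pass without control replicate 1 (log2 difference 1.80) and HSPA5 without control (1.38), bacteria (1.63) or red blood cell (1.61) replicate 1. With all arrays these were 1.90 and 1.57. After quantile normalization 87 of the 88 calls stayed, which argues against a difference in the scale of whole arrays. The deposited arrays had already been scaled to one level, so this was a mild test. It does not address effects on single probe sets or a batch of hybridization. RNA degradation and unequal RNA input stayed open: adjusted for group, replicate 1 differed from the others by a log2 of 0.0417 in the 3-prime to 5-prime ratio of EEF1A1 (95% interval -0.60 to 0.68), -0.14 in that of GAPDH (-0.42 to 0.13) and 0.530 in poly-A spikes (-0.11 to 1.17), where it was the highest of its group in 3 of 4 groups. Of 81 ways to pick 1 array per group, 1 gave as many calls, the real one with 88, and the highest other gave 1. This rank is no test of chance, as the split was picked because replicate 1 stood apart in the same arrays. Every other way also leaves replicate 1 arrays among the rest, which widens the residual. Stress or growth-factor signalling at collection stayed open, since 1 of the 3 lists passed with an estimated correlation, and no label sets replicate 1 apart.

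The dimmer OAZ1 probe set and CXCL8 were higher with red blood cells. The other OAZ1 probe set had a log2 fold change of -0.0432 (95% interval -0.59 to 0.50), which goes with a difference in one probe set only, although a bright transcript could hide a small rise. RNA from the added blood cells stayed open. Of the 4 values of HBB and ALAS2 in red blood cell replicates 2 and 3, 0 lay above all arrays without red blood cells, but AHSP, left out by the filter, had 52 and 52.3 there against 4.5 to 14.2 without red blood cells. These AHSP signals lay below 95.5, the highest signal of the control probe sets without a porcine target. HBB had 17.1 and 13.4 in the same 2 arrays. The verdict that this stayed open was set after the AHSP values were seen.

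Each of the 6 comparisons passed 0 probe sets, and the 10 splits of its 6 arrays into 3 and 3 are too few for a share under 0.05; the highest other split passed 1 for bacteria against cells alone and for sperm against bacteria, and 0 for the 4 others. The F test passed 0 and the highest of the other splits of the 12 arrays passed 1. All 100 splits reach a count of 0 by construction, so these counts say nothing about chance. At an unadjusted p under 0.05, 50 of the 100 splits gave at least the 908 probe sets of the real groups, but these splits mix the replicate numbers, and 19 put 3 arrays of one number in a group. Of 100 splits that keep 1 array of each number in each group, as the real groups do, 4 gave at least 908, the real one included, and the highest other gave 926. That share is just under 0.05 in 1 random draw of splits chosen after the result was seen, which is weak evidence of a difference among the groups, and it names no probe set. In the 2400 brightest probe sets with replicate 1 as a batch term, 6 splits keep 1 replicate 1 array on each side, too few for a share under 0.05. The counts at an unadjusted p under 0.05 were 184 with bacteria (highest other 117), 181 with red blood cells (124) and 163 with sperm (232) against cells alone.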

How the results depend on the processing

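Alternatives that were added after the results were seen are named as such. Counts of probe sets stayed the same in 179 of 188 alternatives, named genes kept their direction and side of the threshold in 1231 of 1236 with 5 stronger and 0 reversed, counts of lists stayed in 160 of 162 and list shifts in 161 of 162, with 1 stronger. The named genes all had the 3 arrays of a group on one side of the other 3. Leaving out an array or changing the pseudocount could therefore not reverse them, and the 0 does not test their direction. None had passed, so keeping the side of the threshold meant not passing. The main counts of probe sets and of lists were also 0, so a count that stayed the same stayed at 0. Fits with fewer arrays have less power, so such counts say little about an absence of differences. With a pseudocount of 1, sperm against cells alone passed 2 probe sets, sperm against bacteria 3, sperm against red blood cells 2 and the F test 1; dim probe sets gain weight by construction. Leaving out each array gave 0 to 1 probe sets for red blood cells against cells alone, sperm against red blood cells, bacteria against red blood cells and the F test, and 0 to 1 lists for red blood cells against cells alone. The 1 probe set, of OAZ1, passed only without red blood cell replicate 1, the lowest of its group. Without an array of the controls the correlations were 0.597 to 0.608 for bacteria and sperm, 0.600 to 0.612 for bacteria and red blood cells and 0.592 to 0.601 for sperm and red blood cells, as fewer shared controls raise them by construction.

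With the replicate block over the 16799 probe sets 0 passed in the 6 comparisons, and 892 to 1012 had an unadjusted p under 0.05; with the lowest 85% also left out, 1 passed for sperm against red blood cells (limma adjusted p of 0.0478). After the group means were taken out, same-numbered arrays correlated at 0.000913 to 0.0932, with 0 of 18 pairs over 0.1, and 10 of 12 arrays correlated best with their own number. With the lowest 75% left out, 10 of 18 same-numbered pairs and 1 of the 12 pairs of replicates 2 and 3 were over 0.1, and 11 of 12 arrays correlated best with their own number. In the 2400 brightest these were 18 of 18, 10 of 12 and 10 of 12. For number 1 the values argue for variation shared across groups. In the 2400 brightest, replicate 1 arrays correlated at 0.478 to 0.627 with each other. With replicate 2 they correlated at -0.453 to -0.214 and with replicate 3 at -0.409 to -0.252. With the group means taken out, the 3 values of a group sum to 0. Positive correlations among replicate 1 arrays thus bring negative ones with replicates 2 and 3. They also bring positive ones, on average, among the arrays of replicates 2 and 3, so only those among replicate 1 arrays count here. Over the 16799 the lowest correlation among replicate 1 arrays was 0.0739, and the highest with replicate 2 was -0.0202. Whether the numbers also pair replicates 2 and 3 stayed open, and the main comparisons and the simulations do not use the numbers. Replicate 1 as a batch term with the lowest 90% left out, added after seeing the data, passed 3 for bacteria against cells alone, SRRM2 among them (log2 fold change -1.22, limma adjusted p of 0.0454), with 2400 tested. It was 1 of 108 combinations of 6 filters, 3 designs and 6 comparisons, of which 106 had no call and the other was that with the replicate block. The cause was not tested. The count for replicate 1, itself added after seeing the data, ranged from 44 with a pseudocount of 1 to 345 with trend and robust priors, and from 7 to 53 with an array left out.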

Other observations

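The tests named here were chosen after the results were seen. In the 2400 brightest probe sets the residuals of replicate 1 arrays correlated at 0.478 to 0.627. Those of replicate 2 arrays correlated at 0.152 to 0.351 and those of replicate 3 arrays at 0.220 to 0.310. Replicates 2 and 3 correlated with each other at 0.0593 to 0.294. Residuals sum to 0 within a group, so the values for replicates 2 and 3 follow in part from those for replicate 1. The hybridization spikes, as the log2 difference of E. coli bio and cre, had means of -3.34 in cells alone, -3.39 with bacteria, -3.33 with sperm and -3.34 with red blood cells.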
